A study of Mus musculus with 4 samples.

How the data were processed

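RNA was measured in 4 libraries, each made from the forelimb bud pair of an individual mouse embryo at E11.5, with 2 libraries of the Smarcc1 conditional knockout and 2 of the control. Per the labels, 310 and 330 ng of RNA went into the knockout libraries and 340 and 580 ng into the control libraries, every sample had an RNA integrity number of 10, and sequencing was on a DNBseq instrument. The authors deposited a table of TPM values (an abundance scaled for transcript length and library total) with 35727 Ensembl gene identifiers and 4 columns, each summing to 1000000. The submitters' processing notes name Salmon 1.9.0 and the mm10 genome build without giving their order or settings. The transcript set and the way transcripts were summed to genes are not given in the sources used here. Column names were matched to sample titles, with 1 column name carrying an extra letter that its title lacked.

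TPM keeps no record of depth, so the number of reads behind each value is unknown, no count test was run and no counting interval is given. Precision rests on the spread between embryos, with n = 2 per genotype. An exact permutation test of 2 against 2 libraries cannot give a two-sided p below 0.333, so single values have no permutation test here, and p-values come from a model that shares its estimate of the spread across genes.

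Identifiers were matched to gene symbols for 35422 genes (99.2%), and the values of 38 symbols found more than once were summed, which left 35689 genes. Coordinates come from the GENCODE annotation of the same build, mm10, and are counted from 1. Genes with a TPM of at least 1 in at least 2 libraries were tested, 12809 in all. Values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), without covariates, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. Fold changes are on the log2(TPM + 1) scale, knockout minus control, which understates the change of genes with low TPM. In libraries where a gene is listed at 0 the value may be a failed estimate, so such genes are given by library and without a fold. Genes that share sequence with near-identical copies, such as processed pseudogenes and the alpha-globin pair, are uncertain because Salmon can divide their reads between copies.

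For 18 gene lists, camera tested each list against the other genes with a preset correlation between genes of 0.01, adjusted over the 18 lists. Each was repeated with an estimated correlation and with fry, which asks whether the genes of a list move, on balance, one way. A further list of sex-linked genes was read per library and not tested, and no fold change is given for its genes. The genes named are Smarcc1; 10 genes of limb patterning named whatever their result; the 10 largest rises and 10 largest falls among genes past the threshold, with separated groups and a higher group mean of at least 5 TPM, leaving out unnamed gene models, pseudogenes and sex-linked genes; and in each list up to 4 members with the smallest p-values. Some genes that this rule picks are not reported here. Genes outside this rule, such as members behind a list's count, were chosen after their values were seen. The groups, the tests, the lists, this rule and the alternatives, other than those stated to have been added later, were set before the data were examined.

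The alternatives were pseudocounts of 0.1 and 5, no filter on low values, a filter at a TPM of 5, median-ratio scaling, quantile normalization, somite stage as a block, no variance trend, a robust variance estimate, removal of sex-linked and erythroid genes, each library left out in turn, and a threshold of 0.1. A restriction to protein-coding genes was added after the data had been seen. For genes that did not pass, log2 fold changes with a library left out are mostly given where the gene passed in that fit. This favours the larger fold, and the fold with the other library left out is often not given. The block for somite stage pairs libraries by the stage in the labels, 40 or 39 somites, not by replicate number. Deviations from the genotype means at the same stage correlated across 12805 genes (Pearson 0.218, Spearman 0.364), genes being not independent replicates. Sex coincided with stage, so the block removes both. The block also uses up part of the 2 residual degrees of freedom of the model without stage. Its p-values and SE therefore lean more on the spread shared across genes.

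The test was tested on simulated data for this comparison before use, in 20 runs with 200 changed genes among 12809. It called 0.221% of genes changed by 0.5 on the log2 scale, 22.6% of those changed by 1 and 69.2% of those changed by 2, and 1.62% of its calls were false. By these simulated rates, changes under 2-fold were mostly beyond reach. The simulated noise was drawn for each gene alone, whereas real deviations at the same stage correlated across genes. Its size came from residual spreads with 2 degrees of freedom, which are themselves uncertain. The simulated spread may thus vary more between genes than the real one, which would lower the share called. The rates may therefore not carry over to the real calls.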

Results

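Forelimb buds of mouse embryos at E11.5 were profiled by RNA sequencing with and without conditional knockout of Smarcc1 in limb mesenchyme. Smarcc1 encodes BAF155, a core subunit of the BAF (SWI/SNF) chromatin remodelling complex. Knockout embryos were homozygous for a conditional Smarcc1 allele and carried PrxCre, a Cre transgene active in limb bud mesenchyme, and controls carried the same alleles without Cre. Each of the 4 libraries held the forelimb pair of an individual embryo, and each genotype had 1 embryo with 40 somites (replicate 1) and 1 with 39 somites (replicate 2). Between 12555 and 12689 genes reached a TPM of 1 in each library, and the read depth is unknown. Mitochondrial transcripts took 10.1% and 7.58% of TPM in the knockout libraries with 40 and 39 somites, and 9.91% and 8.05% in the control libraries. The Y-linked gene Ddx3y stood at 0.0498 and 28.3 TPM in the knockout libraries with 40 and 39 somites and at 0.013 and 30.2 TPM in the control libraries. Eif2s3y, Kdm5d and Uty, also Y-linked, were split in the same way. Eif2s3y stood at 0.151 and 50.6 TPM in the knockout and 0.198 and 46.0 TPM in the control. Kdm5d stood at 0.504 and 25.7 against 0.343 and 22.1 TPM. Uty stood at 0.163 and 13.5 against 0.0128 and 14.5 TPM. Sex was thus balanced between the genotypes and coincided with somite stage.

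Smarcc1 itself fell in the knockout forelimbs to 0.365 of its control level. Its TPM was 46.2 and 38.4 in the knockout libraries against 112 and 119.6 in the control libraries, and its log2 fold change was -1.44 ± 0.13 (SE, n = 2 per genotype; limma, Benjamini-Hochberg adjusted p = 0.0117). The gene (ENSMUSG00000032481) lies on chromosome 9 of mm10 from 110117708 to 110240178. The tissue also holds cells outside the PrxCre domain, such as ectoderm, blood and endothelium. A TPM for the whole gene can also count transcript left from a recombined allele. The remaining level is therefore not a measure of unrecombined cells or of intact transcript. With no filter on low values the fold was the same and the adjusted p from limma with Benjamini-Hochberg adjustment was 0.111.

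The first question was which genes differ in the forelimbs of Smarcc1 conditional knockouts. Pitx1, a homeobox gene of the hindlimb, Rspo3, a secreted activator of WNT signalling, and the collagen gene Col1a1 were among the genes that rose, and the homeobox genes Msx1, Msx2, Lhx2 and Lhx9 were among those that fell. In all, 167 of 12809 genes passed limma with Benjamini-Hochberg adjustment at 0.05, with 104 higher and 63 lower in the knockout, and 136 of these differed by at least 2-fold, 88 higher and 48 lower. At an unadjusted p under 0.05 there were 1752 genes, 869 higher and 883 lower. In all 167 genes both knockout libraries lay on the same side of both controls; 43.9% of all tested genes were separated in this way, against 33.3% by chance. Of the 167 genes, 156 are protein-coding, and several of the others, such as Gm1821, are processed pseudogenes whose reads can be shared with a parent gene. With somite stage in the model, 533 genes passed, 266 higher and 267 lower, and all 167 were among them. Of the 533 genes 49.9% were higher, against 62.3% without stage. Since stage is balanced between the genotypes, the block leaves every fold change and its sign as they were. With no filter on low values 0 genes passed in limma and 2338 had an unadjusted p under 0.05. Leaving out control replicate 1 or 2 gave 59 and 50 genes, of which 50 and 43 were among the 167, while leaving out knockout replicate 1 or 2 gave 646 and 501.

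The largest rise by the naming rule was that of Pitx1 (chromosome 13, 55825051 to 55836192), from 0.110 and 0.165 TPM in the controls to 14.9 and 10.4 TPM in the knockouts. Its log2 fold change was 3.56 ± 0.20 (SE, n = 2 per genotype; limma, Benjamini-Hochberg adjusted p = 0.00422). Tac1, which encodes the precursor of the neuropeptide substance P, rose from 2.21 and 1.89 TPM to 30.3 and 24.5 TPM. Pou4f1, a POU-domain transcription factor of sensory neurons, rose from 1.03 and 1.16 TPM to 20.1 and 11.1 TPM. Brachyury, the T-box gene T, rose from 2.69 and 3.06 TPM to 32.3 and 14.2 TPM. The other named rises on the log2 scale were 3.23 ± 0.17 for Nap1l5, 3.02 ± 0.15 for Lrrn3, 2.70 ± 0.28 for Apela, a peptide ligand of the apelin receptor, 2.29 ± 0.32 for Gmnc, 2.29 ± 0.19 for the cell-surface protein gene Thy1 and 2.25 ± 0.16 for Glt8d2. Tubb3, Stmn2 and Elavl4, general neuronal genes of the neural list, had log2 fold changes of -0.27 ± 0.14, -0.02 ± 0.19 and -0.04 ± 0.16 and did not pass. The calls for T and Gmnc ended under median-ratio and quantile scaling, at a pseudocount of 5 and when control replicate 1 or 2 was left out (limma adjusted p of 0.104 and 0.101 for T and 0.105 each time for Gmnc), and that for T also with a robust variance.

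The largest falls by the same rule were in Gja3, which encodes a connexin, at -2.47 ± 0.21 on the log2 scale (15.4 and 23.2 TPM in the controls, 2.48 and 2.72 TPM in the knockouts), and in the WNT enhancer Rspo4, at -2.19 ± 0.26. Lhx2, a LIM homeobox gene of distal limb mesenchyme, fell from 32.4 and 49.2 TPM to 8.26 and 10.6 TPM (log2 fold change -1.98 ± 0.22). Msx1 fell from 81.5 and 108.9 TPM to 27.0 and 27.8 TPM, with a log2 fold change of -1.75 ± 0.16, and Msx2 from 36.4 and 33.8 TPM to 13.4 and 8.53 TPM, at -1.62 ± 0.20. The remaining named falls were -2.12 ± 0.15 for Ifitm1, -1.93 ± 0.20 for Rprm, -1.91 ± 0.22 for Vwde and -1.74 ± 0.15 for Fgf13. Limma's Benjamini-Hochberg adjusted p for these 9 genes lay between 0.00694 for Ifitm1 and 0.0283 for Msx2. The calls for Msx2 and Vwde ended under median-ratio and quantile scaling. Without control replicate 1 limma's adjusted p was 0.0917 for Msx2, 0.0753 for Vwde and 0.0584 for Rprm, and without control replicate 2 it was 0.0828 for Msx2 and 0.0550 for Rspo4 and Fgf13.

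**Figure D1:**
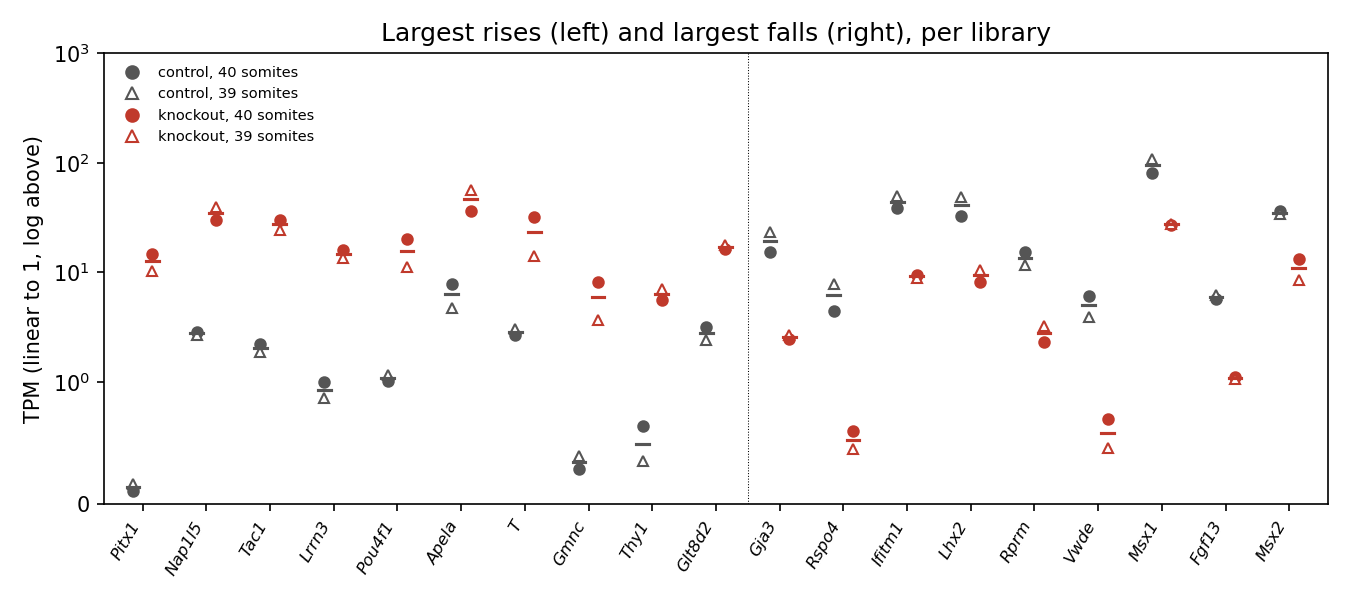
TPM of the 10 named genes with the largest rise and the 9 with the largest fall, on an axis that is linear up to 1 and logarithmic above, with a point per library (grey for control, red for knockout; filled circle for 40 somites, open triangle for 39 somites) and a bar at each group's mean. In each of the 19 genes both knockout points lie on the same side of both control points, and Pitx1 goes from below 1 TPM in the controls to 14.9 and 10.4 TPM in the knockouts.

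The second question, raised by the title of the series, was whether genes held down by the repressor form of GLI transcription factors are released when BAF is impaired. Among Hedgehog target genes, Sall1 and Tbx3 fell, from 26.2 and 34.6 to 12.5 and 13.2 TPM and from 19.9 and 16.0 to 6.21 and 8.41 TPM (log2 fold changes -1.16 ± 0.16 and -1.19 ± 0.18, n = 2 per genotype; limma, Benjamini-Hochberg adjusted p = 0.0351 and 0.0465). The direct target Gli1 stood at 41.9 and 38.8 TPM in the knockouts and 29.5 and 29.7 TPM in the controls, while Hhip, which encodes a Hedgehog-binding inhibitor, stood at 2.73 and 4.51 against 1.45 and 1.14 TPM. Neither passed over all genes (0.43 ± 0.11 and 0.98 ± 0.23; limma, Benjamini-Hochberg adjusted p = 0.162 and 0.131). The log2 fold change of Hhip was 1.265 without knockout replicate 1, the knockout library nearer the controls. Sall1 lost its call without control replicate 2 (0.0821), and Tbx3 without control replicate 1 or 2 (0.138 and 0.0848). Ptch1, the Hedgehog receptor and a direct target, stood at 28.1 and 28.0 TPM in the knockouts and 28.0 and 26.3 TPM in the controls, a log2 fold change of 0.05 ± 0.11 with a 95% interval from -0.22 to 0.31. The 95% intervals were 0.03 to 0.79 for the BMP antagonist gene Grem1, -0.49 to 0.13 for Hand2 and -0.62 to 0.24 for Hoxd13, and none of these passed (limma, Benjamini-Hochberg adjusted p = 0.322, 0.627 and 0.729). Without control replicate 2 the log2 fold change of Hoxd13 was 0.00502, and it did not pass there either (adjusted p = 0.992).

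Of the 19 Hedgehog target genes tested, 0 rose, 2 fell and 17 did not pass over all genes by limma, and at an unadjusted p under 0.05 there were 6 higher and 4 lower. By limma adjusted over the list alone, 4 were higher and 3 lower, the 4 being Gli1, Hhip, Ccnd2 and Bmp2 and the 3 Sall1, Tbx3 and Hoxd11. Ccnd2, Bmp2 and Hoxd11 are named after their values were seen, and the log2 fold change of Hoxd11 was -0.81 without knockout replicate 2. With somite stage in the model, 1 was higher (Ccnd2) and 3 lower (Sall1, Tbx3 and Hoxd11) over all genes, and Gli1 had a limma Benjamini-Hochberg adjusted p of 0.0550. The median log2 fold change of the list was 0.05 and the mean -0.03, and camera gave an adjusted p of 0.970 in the downward direction, so that median and test differed in sign. Fry's test for change in either direction gave an adjusted p of 0.0173, as it did for the Hedgehog component and WNT lists, and 0.0301 for the BMP and the proximodistal and dorsoventral lists. In simulated data of this design 22.6% of genes changed by 1 on the log2 scale were called, so genes that did not pass are not shown to be unchanged. The list does not separate genes held down by GLI repressor from other Hedgehog targets. Whole forelimb buds do not show where a gene is expressed, and Shh itself fell, as given below. The list result therefore does not answer whether such genes are released.

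Shh, the ligand made by the posterior signalling centre of the limb bud, fell from 17.5 and 14.6 TPM in the controls to 4.59 and 6.38 TPM in the knockouts (log2 fold change -1.41 ± 0.18, n = 2 per genotype; limma, Benjamini-Hochberg adjusted p = 0.0319). Shh lies on chromosome 5 from 28456815 to 28467256. Gli3, the main GLI repressor gene of the limb bud, stood at 20.1 and 24.2 TPM in the knockouts and 23.0 and 29.4 TPM in the controls, and did not pass (-0.23 ± 0.16; limma, Benjamini-Hochberg adjusted p = 0.629). Boc, a Hedgehog co-receptor gene, stood at 18.5 and 22.8 against 10.8 and 13.9 TPM. Evc, which encodes a ciliary protein of the pathway, stood at 36.1 and 36.2 against 24.8 and 26.6 TPM. Iqce stood at 16.2 and 18.1 against 13.0 and 14.0 TPM. These did not pass over all genes, and with somite stage in the model Boc and Evc did (limma, Benjamini-Hochberg adjusted p = 0.0279 and 0.0458). Of the 17 pathway components tested, 0 rose and 1, Shh, fell over all genes by limma, with 3 higher and 2 lower at an unadjusted p under 0.05. The log2 fold change of Boc was 0.84 without knockout replicate 1, the knockout library nearer the controls. With adjustment over the list alone 2 were higher and 1 lower, as with stage in the model. Their median was 0.07 and their mean -0.02, and camera gave an adjusted p of 0.855 upward, with the mean on the other side of 0. The calls for Shh and Tbx3 ended under median-ratio and quantile scaling and when control replicate 1 or 2 was left out (limma adjusted p of 0.0942 and 0.0699 for Shh, 0.138 and 0.0848 for Tbx3). Their log2 fold changes ran from -1.61 to -1.01 for Shh and -1.39 to -0.90 for Tbx3 across 15 alternatives, and the call for Tbx3 ended also without the variance trend. The call for Sall1 ended without control replicate 2 (0.0821).

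**Figure D2:**
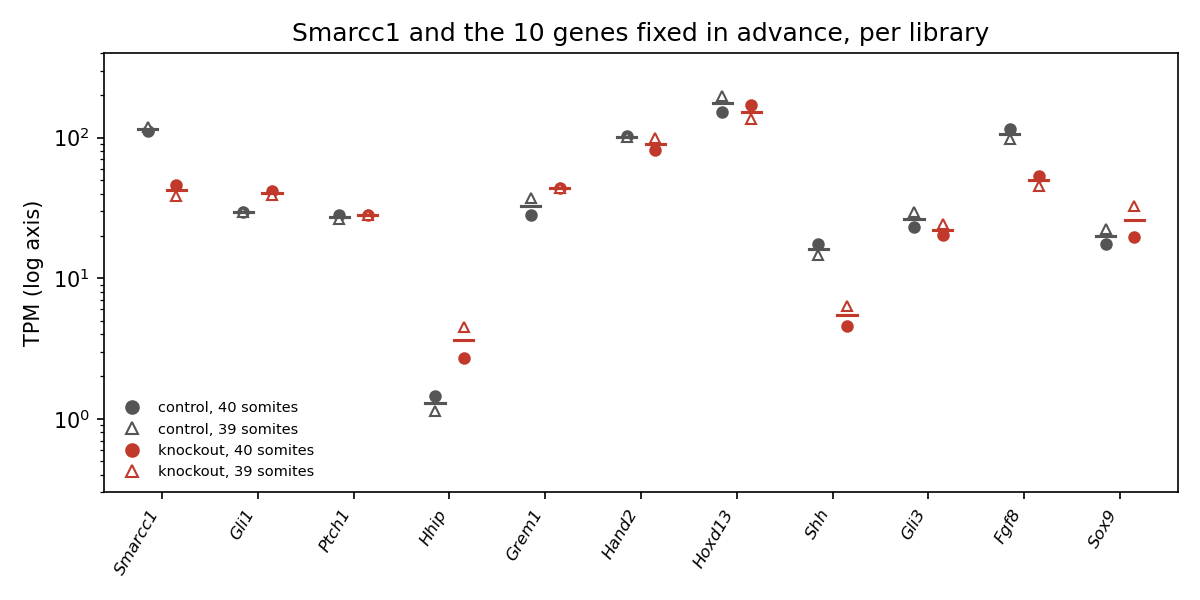
TPM on a log axis of Smarcc1 and the 10 limb genes named whatever their result, with a point per library (grey for control, red for knockout; filled circle for 40 somites, open triangle for 39 somites) and a bar at each group's mean. Smarcc1, Shh and Fgf8 lie lower in both knockouts, at 42.3, 5.48 and 49.6 TPM on average against 115.8, 16.1 and 107 TPM, while Ptch1 averages 28.0 against 27.1 TPM.

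Fgf8 and Sp6, genes of the apical ectodermal ridge, the epithelial signalling centre at the limb tip, fell in the knockouts. Fgf8, the ridge growth factor, fell from 115.8 and 98.2 TPM to 53.7 and 45.6 TPM (log2 fold change -1.09 ± 0.14), and Sp6, a ridge transcription factor gene, from 26.4 and 21.6 TPM to 9.67 and 7.29 TPM (-1.40 ± 0.18), each with n = 2 per genotype and a limma Benjamini-Hochberg adjusted p of 0.0283. En1, expressed in ventral ectoderm, stood at 3.54 and 2.46 against 9.65 and 7.22 TPM. The FGF target Etv4 stood at 52.9 and 53.6 against 68.9 and 73.1 TPM. These did not pass (limma, Benjamini-Hochberg adjusted p = 0.0589 and 0.162), and passed with somite stage in the model (0.0175 and 0.0490). The log2 fold change of En1 was -1.436 without knockout replicate 1 and -1.045 without knockout replicate 2. Of the 20 genes of the FGF and ridge list, 0 rose, 2 fell and 18 did not pass (at an unadjusted p under 0.05, 0 were higher and 7 lower in limma). When adjusted over the list alone 4 fell, and 4 with stage in the model. Camera called the list downward with an adjusted p of 7.99e-05 and a median of -0.24, and the adjusted p was 0.825 with an estimated correlation and 0.531 with fry. Markers of the surface ectoderm were lower beside them: all 12 lay below 0, with a median of -0.43. The calls for Fgf8 and Sp6 ended under median-ratio and quantile scaling and when control replicate 1 or 2 was left out (limma adjusted p of 0.0872 and 0.0550 for Fgf8, 0.0895 and 0.0573 for Sp6).

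Surface ectoderm markers fell as a list by camera (adjusted p = 0.000643), with 0 of 12 passing singly over all genes or over the list alone in limma and 4 at an unadjusted p under 0.05. Their adjusted p was 0.876 with an estimated correlation. The tight junction gene Cldn6 stood at 39.4 and 27.4 TPM in the knockouts and 61.3 and 43.9 TPM in the controls. Grhl3 stood at 8.92 and 4.20 against 14.1 and 9.67 TPM. The keratins Krt8 and Krt18 stood at 18.5 and 19.4 against 34.9 and 25.0 TPM and at 23.6 and 20.4 against 39.4 and 27.7 TPM. With somite stage in the model 3 markers were lower singly, Cldn6, Grhl3 and Perp (limma, Benjamini-Hochberg adjusted p = 0.0230, 0.0496 and 0.0251), Perp being chosen after its values were seen. The log2 fold changes of the same 3 were -0.90, -1.29 and -1.015 without knockout replicate 1. For Cldn6 and Grhl3 that was the knockout library nearer the controls. Camera's call was lost without knockout replicate 2 and without control replicate 1. Fits without a library leave stage and sex unbalanced between the genotypes. Within each stage the mean marker level, knockout minus control, was -0.45 log2 units at 40 somites and -0.46 at 39.

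Among genes of proximodistal and dorsoventral patterning, Msx1, Msx2, Lhx2 and Lhx9 fell. Lhx9 went from 68.8 and 105.1 TPM to 32.4 and 33.2 TPM (log2 fold change -1.35 ± 0.20, n = 2 per genotype; limma, Benjamini-Hochberg adjusted p = 0.0416). Of the 20 genes, 0 rose, 4 fell and 16 did not pass, with 1 higher and 7 lower at an unadjusted p under 0.05 in limma. Adjusted over the list alone, 1 was higher (Lmx1b) and 5 lower (those 4 and Prrx1). With stage in the model Hoxd10 joined them, for 1 higher and 6 lower. Lmx1b, Prrx1 and Hoxd10 are named after their values were seen. The log2 fold change of Lmx1b was 0.91 without knockout replicate 1. Camera called the list downward with an adjusted p of 9.64e-05 and a median of -0.38, and the adjusted p was 0.876 with an estimated correlation and 0.741 with fry. Lhx9 lost its call under quantile normalization, without the variance trend and without control replicate 2 (0.0550), and Msx2 without control replicate 1 or 2 (0.0917 and 0.0828).

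Alx4 and Asb4, genes of the anterior limb bud, passed in limma with somite stage in the model but not without it. Alx4 stood at 2.99 and 5.36 TPM in the knockouts against 10.5 and 14.1 TPM in the controls. Asb4 stood at 249.6 and 293.7 against 387 and 562.3 TPM. Alx1 stood at 2.44 and 3.60 against 1.13 and 1.61 TPM. Irx3 stood at 4.85 and 9.20 against 3.79 and 4.87 TPM. With somite stage in the model Alx4 and Asb4 were lower (limma, Benjamini-Hochberg adjusted p = 0.0158 and 0.0299). Without knockout replicate 1 the log2 fold changes of Alx4, Alx1 and Irx3 were -1.055, 0.97 and 0.94. Those of Alx4 and Asb4 were -1.73 and -0.90 without knockout replicate 2. For Alx1, Irx3 and Asb4 the library left out was the knockout nearer the controls. With all libraries and no stage, 0 of 9 genes of the list passed over all genes in limma and 3 had an unadjusted p under 0.05. Adjusted over the list alone, Alx1 was higher and Alx4 and Asb4 lower, 1 and 2 genes, and camera's adjusted p was 0.363.

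In the WNT list Rspo3 rose from 7.59 and 9.14 TPM to 24.8 and 27.1 TPM (log2 fold change 1.53 ± 0.14; limma, Benjamini-Hochberg adjusted p = 0.0119), and Tcf7, a nuclear effector of WNT signalling, fell from 36.0 and 42.9 TPM to 22.4 and 21.2 TPM (-0.82 ± 0.13; limma, Benjamini-Hochberg adjusted p = 0.0499). Its relative Lef1 stood at 19.0 and 16.3 against 30.5 and 36.1 TPM. The secreted WNT inhibitor gene Wif1 stood at 34.0 and 38.7 against 24.2 and 24.4 TPM. Both passed with somite stage in the model (limma, Benjamini-Hochberg adjusted p = 0.0385 and 0.0394). The log2 fold change of Lef1 was -0.98 without knockout replicate 1 and -0.78 without knockout replicate 2. Of 16 genes, 1 rose, 1 fell and 14 did not pass, with 2 higher and 3 lower adjusted over the list alone and 2 higher and 2 lower with stage in the model. The third lower gene over the list alone was Nkd1, named after its values were seen. Camera's adjusted p was 0.363. Tcf7 lost its call in 6 of 15 alternatives, among them both other pseudocounts and control replicate 1 (0.0753) or 2 (0.139) left out.

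In the BMP list Bambi, a pseudoreceptor gene induced by BMP signalling, fell from 21.0 and 18.1 TPM to 9.69 and 7.57 TPM (log2 fold change -1.10 ± 0.16; limma, Benjamini-Hochberg adjusted p = 0.0409), and the other 13 genes did not pass. Bmp7 stood at 20.9 and 19.8 against 26.2 and 27.1 TPM. Id2 stood at 225.3 and 251 against 199.4 and 192.2 TPM. Id3 stood at 152.5 and 143.1 against 110.2 and 136.7 TPM. In the cartilage list Col9a3 fell from 3.53 and 4.01 TPM to 0.710 and 1.24 TPM (-1.28 ± 0.19; limma, Benjamini-Hochberg adjusted p = 0.0432), and the other 14 genes did not pass. Sox9, the master regulator of cartilage, stood at 19.5 and 32.5 against 17.4 and 22.6 TPM (0.33 ± 0.25; limma, Benjamini-Hochberg adjusted p = 0.650). Its log2 fold change was 0.69 without knockout replicate 1. Without knockout replicate 2 its log2 fold change was -0.02. Runx2 stood at 2.52 and 1.51 against 0.572 and 0.963 TPM. Its log2 fold change was 1.003 without knockout replicate 2, the knockout library nearer the controls. Gdf5 stood at 0.588 and 0.429 against 1.10 and 1.36 TPM. Wwp2 stood at 47.7 and 47.5 against 54.4 and 66.9 TPM. By adjustment within each list, 1 BMP gene and 1 cartilage gene were lower and 0 higher, and camera's adjusted p was 0.433 and 0.508. The calls for Bambi and Col9a3 ended under median-ratio and quantile scaling and when control replicate 1 or 2 was left out (limma adjusted p of 0.127 and 0.0895 for Bambi, 0.126 and 0.150 for Col9a3), and that for Col9a3 also at a pseudocount of 0.1.

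Among p53 target and apoptosis genes Pmaip1, which encodes the pro-apoptotic protein NOXA, rose from 98.3 and 129 TPM to 225 and 225.3 TPM (log2 fold change 0.99 ± 0.15; limma, Benjamini-Hochberg adjusted p = 0.0431), and the other 16 genes did not pass. Ccng1 stood at 24.2 and 22.6 against 18.6 and 17.99 TPM. Phlda3 stood at 12.3 and 10.5 against 17.7 and 13.2 TPM. Bcl2l11 stood at 13.9 and 16.5 against 18.3 and 18.4 TPM. Adjusted over the list alone 1 was higher and 0 lower, and camera gave an adjusted p of 0.963, with a median of -0.02 against a mean of 0.04 and an upward test. Pmaip1 lost its call under quantile normalization, without the variance trend and without control replicate 1 (0.0856).

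Of the 25 other BAF subunit genes tested, 0 passed in limma over all genes or over the list alone and 1, Dpf1, had an unadjusted p under 0.05, and camera's adjusted p was 0.753. Dpf1 stood at 10.1 and 8.996 TPM in the knockouts and 14.1 and 17.1 TPM in the controls (log2 fold change -0.65 ± 0.15; limma, Benjamini-Hochberg adjusted p = 0.127). Smarca2, an ATPase subunit gene, stood at 47.9 and 44.1 against 50.7 and 57.3 TPM. Smarcd2 stood at 78.3 and 73.3 against 61.5 and 66.3 TPM. Smarcd3 stood at 22.9 and 20.6 against 16.1 and 19.2 TPM. Of the 21 cell cycle genes 0 passed in limma by either adjustment and 0 had an unadjusted p under 0.05, and camera's adjusted p was 0.363. Mcm5 stood at 195.7 and 240.2 against 152.1 and 194.4 TPM. Mcm4 stood at 131.9 and 149.4 against 111.5 and 128 TPM. Aurka stood at 131.9 and 143.1 against 109.1 and 129.9 TPM. Ccne2 stood at 48.4 and 49.9 against 61.5 and 56.0 TPM.

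Markers of other cell types in the bud were compared in the same way, and 0 of their genes passed singly over all genes by limma, while at an unadjusted p under 0.05 there were 2 myogenic, 1 macrophage, 0 endothelial, 3 erythroid, 0 neural and 2 immediate early genes. Myogenic markers rose as a list by camera (adjusted p = 0.0383, median 0.31, 9 of 10 above 0), and the adjusted p was 0.876 with an estimated correlation. Myod1 stood at 5.80 and 4.13 TPM in the knockouts and 2.84 and 2.35 TPM in the controls. Chrna1 stood at 1.79 and 3.53 against 0.851 and 0.733 TPM. Lbx1 stood at 6.33 and 11.7 against 5.83 and 4.69 TPM. Myf5 stood at 8.999 and 11.9 against 9.10 and 6.79 TPM. Macrophage markers fell as a list (camera, adjusted p = 0.0101, median -0.37, 8 of 9 below 0), and the adjusted p was 0.876 with an estimated correlation. Adgre1 stood at 0.468 and 0.381 against 1.17 and 2.00 TPM. Fcer1g stood at 4.41 and 3.61 against 4.46 and 7.30 TPM. Cx3cr1 stood at 0.917 and 0.701 against 1.13 and 1.92 TPM. C1qb stood at 3.99 and 2.82 against 4.14 and 5.43 TPM. Adjusted over the list alone, 2 myogenic genes were higher, Myod1 and Chrna1, and 0 macrophage genes differed. Without knockout replicate 1 the log2 fold changes of Chrna1, Lbx1 and Adgre1 were 1.34, 1.02 and -0.89. That of Myod1 was 0.92 without knockout replicate 2. In each case the library left out was the knockout nearer the controls. The myogenic call was lost with somite stage in the model (camera, adjusted p = 0.0696), without knockout replicate 1 (0.4999) and without control replicate 2 (0.694), and the macrophage call without knockout replicate 2 (0.294) and without control replicate 2 (0.183).

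Endothelial, erythroid, neural and immediate early lists were not called by camera, with adjusted p of 0.363, 0.181, 0.314 and 0.363. Leaving out knockout replicate 1 or control replicate 2 gave an upward call of the endothelial list (adjusted p = 0.00377 and 0.00011), and leaving out control replicate 2 one of the erythroid list (0.00088). Pecam1, an endothelial adhesion gene, stood at 14.1 and 18.3 TPM in the knockouts against 8.23 and 16.5 TPM in the controls. Esam stood at 8.49 and 10.5 against 4.47 and 10.1 TPM. Ramp2 stood at 14.8 and 20.5 against 10.7 and 18.2 TPM. Sox18 stood at 6.77 and 9.27 against 3.01 and 6.71 TPM. The globin gene Hba-a1 stood at 1832 and 1833 against 782.5 and 1154 TPM, and was higher adjusted over the list alone and, over all genes, with somite stage in the model (limma, Benjamini-Hochberg adjusted p = 0.0487); its reads can be divided with its near-identical copy. Hba-x stood at 1686 and 1801 against 713.8 and 1422 TPM. Alas2 stood at 18.5 and 20.1 against 10.7 and 18.3 TPM. Hbb-bs stood at 28.4 and 29.2 against 36.2 and 37.6 TPM. The Schwann cell gene Mbp stood at 4.40 and 2.48 against 4.62 and 3.15 TPM. Erbb3 stood at 6.20 and 3.51 against 7.35 and 5.51 TPM. The neuronal gene Tubb3 stood at 7.20 and 7.42 against 8.49 and 9.54 TPM. Junb stood at 2.81 and 3.10 against 4.02 and 5.75 TPM. Jun stood at 6.78 and 7.88 against 9.40 and 10.1 TPM. Dusp1 stood at 6.96 and 9.08 against 8.73 and 10.6 TPM. Hsph1 stood at 116.1 and 129.6 against 111.2 and 118.2 TPM. Without knockout replicate 1 the log2 fold changes of Sox18, Hba-a1 and Hba-x were 0.89, 0.95 and 0.84. That of Hba-a1 was 0.95 without knockout replicate 2. Those of Hba-a1 and Hba-x were 1.23 and 1.29 without control replicate 2, the control nearer the knockouts. For Sox18 and Hba-x, knockout replicate 1 was the knockout nearer the controls. Pecam1, Esam and Ramp2 turned below 0 without control replicate 1, at -0.03, -0.09 and -0.06. Mbp turned above 0 without knockout replicate 2 (0.16) or control replicate 1 (0.06). Adjusted over each list alone, 1 erythroid gene, Hba-a1, was higher, and 0 genes of the other 3 lists differed.

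**Figure D3:**
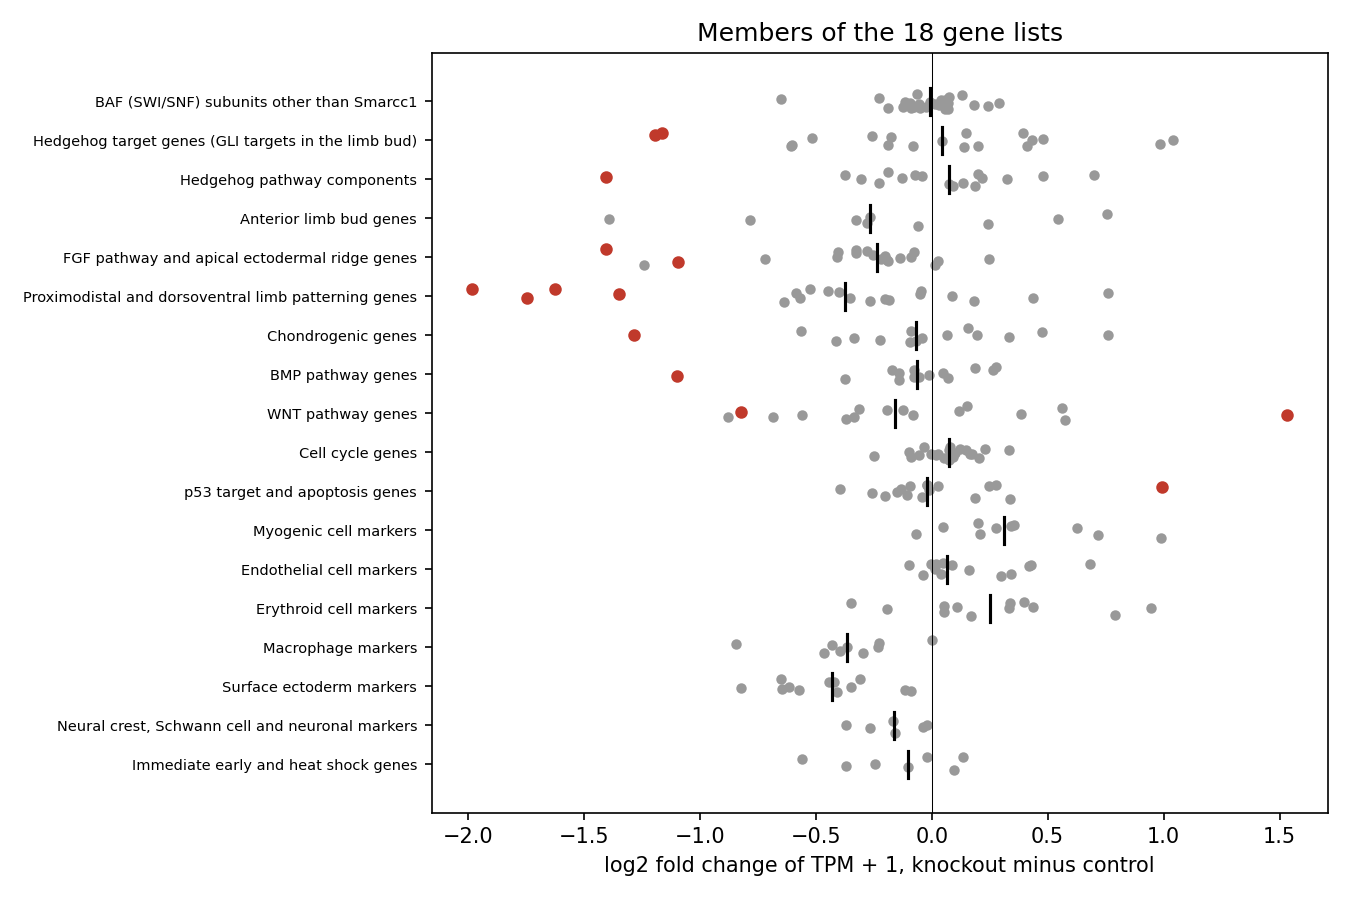
Log2 fold change of TPM + 1, knockout minus control, of each tested member of the 18 gene lists, with a point per gene (red where it passed limma with Benjamini-Hochberg adjustment over all 12809 genes, grey otherwise), shifted vertically at random within its list, and a black bar at each list's median. All 12 surface ectoderm markers lie below 0, and the 4 red points of the proximodistal and dorsoventral list lie between -1.98 and -1.35.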

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

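Of the settings compared here, only the restriction to protein-coding genes was chosen after the results were seen. The 167 genes past the threshold became 0 with no filter on low values (2338 at an unadjusted p under 0.05; limma's prior degrees of freedom fell from 4.16 to 2.12 as 20946 genes were tested), 533 with somite stage as a block, 275 with a robust variance estimate, 306 with protein-coding genes only and 316 at a threshold of 0.1. Without 1 library the count ran from 50 to 646, with the lone library of a genotype assumed to vary like the other genotype's pair. The prior degrees of freedom were 1323 without knockout replicate 1, infinite without knockout replicate 2 and 4.72 without control replicate 2. In the fits without a knockout library a gene's own spread thus carried almost no weight, so passing there is no support for single genes. Leaving out any library also left somite stage and sex unbalanced between the genotypes, so calls lost or gained there can reflect either. In the other settings the count lay between 126 and 196, and all genes among the 167 that could be tested kept their sign in every setting. With separated groups, the sign could not change when a library was left out. Nor could it with another pseudocount, filter, variance estimate or threshold, or with the stage block. Median-ratio scaling and quantile normalization moved the median of all genes by -0.0131 and -0.00801. Smarcc1 stayed at -1.44 with no filter, where its adjusted p was 0.111, and passed in all other settings. Of 30 other named genes past the threshold, 0 passed with no filter; Pitx1, Rspo3 and Msx1 passed in the other 14 settings. Of 63 named genes that did not pass, 11 passed with the stage block, and its effect is stated wherever it changed a call. Without 1 library, log2 fold changes crossed 0 for Hoxd13 (-0.39 to 0.00502), Sox9 (-0.0237 to 0.69), Esam (-0.0898 to 0.93), Pecam1 (-0.0319 to 0.89), Ramp2 (-0.0587 to 0.65) and Mbp (-0.48 to 0.16), none of which had passed. Camera called 5 lists, and 0 were called with an estimated correlation and 0 with fry. Without 1 library camera called 3 to 5 lists, of which 3 or 4 were among those 5 and the others were the endothelial and erythroid lists. Adjusted p with an estimated correlation and with fry was 0.825 and 0.531 for the FGF and ridge list, and 0.876 and 0.741 for each of the proximodistal, myogenic, macrophage and surface ectoderm lists. The myogenic list also lost its call with no filter (0.372), median-ratio scaling (0.0861), quantile normalization (0.0733) and the stage block (0.0696). Without 1 library adjusted p ran from 0.000332 to 0.694 for the myogenic, 0.000517 to 0.294 for the macrophage and 3.64e-11 to 0.549 for the ectoderm list. Lists that were not called turned direction in some settings: Hedgehog targets with no filter (0.805), the stage block (0.955) and 1 library left out (0.715 to 0.984), Hedgehog components (0.625 to 0.878), BAF subunits (0.532 to 0.984), p53 targets (0.659 to 0.984; stage block 0.962) and endothelial markers (0.00011 to 0.819) without 1 library. Where no value above shows it, the cause was not tested. The depth behind TPM is unknown, so the smallest change that sequencing depth allows cannot be given.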

Other observations

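The genes named in this part were chosen after their values were seen, as were the tests of surface ectoderm with stage in the model, of the ectoderm markers as a list, of proximal and of distal genes, and of other splits of the libraries; the tests of ectoderm without stage, of hindlimb genes and of pseudogene parents were set before their results were seen.

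Some genes of connective tissue and extracellular matrix rose in the knockout forelimbs and others fell. Col1a1 rose from 9.61 and 10.7 TPM to 45.1 and 58.5 TPM (log2 fold change 2.23 ± 0.16, n = 2 per genotype; limma, Benjamini-Hochberg adjusted p = 0.00694), and Lox, which encodes a collagen cross-linking enzyme, from 0.795 and 0.715 TPM to 7.50 and 6.33 TPM. Col12a1, Postn, Lum and Pdgfra rose by 1.45 ± 0.17, 1.58 ± 0.21, 1.21 ± 0.13 and 1.03 ± 0.11 on the log2 scale, and the transcription factor gene Osr2, of proximal mesenchyme and connective tissue, by 1.47 ± 0.17. The matrix genes Lama1, Emilin3, Col27a1 and Col9a3 fell, by -1.27 ± 0.16, -1.19 ± 0.17, -0.86 ± 0.13 and -1.28 ± 0.19. Genes of retinoic acid turnover changed in both directions. Rdh10, which encodes an enzyme of retinoic acid synthesis, rose from 8.56 and 8.12 TPM to 19.9 and 21.0 TPM, while Cyp26b1, which encodes the retinoic acid degrading enzyme of distal limb mesenchyme, fell from 80.0 and 117.7 TPM to 35.2 and 39.2 TPM and the retinaldehyde reductase gene Dhrs3 from 13.6 and 14.2 TPM to 6.19 and 6.80 TPM. The calls for Col12a1, Lum, Pdgfra, Osr2 and Dhrs3 were lost without control replicate 1 (limma adjusted p of 0.0745, 0.0584, 0.0597, 0.0781 and 0.0907) and without control replicate 2 (0.0752, 0.0550, 0.0524, 0.0652 and 0.107), and those for Postn, Rdh10 and Cyp26b1 without control replicate 2 (0.0752, 0.0555 and 0.0571). Those for Lama1, Emilin3, Col27a1 and Col9a3 were lost without control replicate 1 (0.0706, 0.0996, 0.135 and 0.126) and without control replicate 2 (0.109, 0.141, 0.139 and 0.150). These groups were not tested for enrichment.

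Neuron-associated genes went both ways, and the list of neural crest, Schwann cell and neuronal markers was not called (0 of 6 genes above 0, median -0.16; camera, adjusted p = 0.314). Islr2 rose from 0.577 and 0.518 TPM to 7.18 and 4.62 TPM, Dcx from 7.79 and 9.80 TPM to 18.5 and 23.0 TPM, and Skor1, listed at 0 in both controls, stood at 4.66 and 5.13 TPM in the knockouts. Rbfox3, a marker of mature neurons, fell from 1.57 and 1.64 TPM to 0.127 and 0.150 TPM, and Tagln3 fell from 17.4 and 20.03 TPM to 9.74 and 7.94 TPM. The calls for Islr2, Dcx, Rbfox3 and Tagln3 were lost without control replicate 1 (limma adjusted p of 0.0584, 0.106, 0.153 and 0.0917) and without control replicate 2 (0.0581, 0.0695, 0.153 and 0.138).

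The fall of the ridge genes Fgf8 and Sp6 went with lower surface ectoderm markers. All 12 of these markers lay below 0, but markers of the same tissue can move together. Their mean level was 4.895 and 4.311 log2 units in knockout replicates 1 and 2, against 5.342 and 4.77 in control replicates 1 and 2. It was lower in the knockout within both stages, by -0.45 log2 units at 40 somites and -0.46 at 39. Across stages, however, knockout replicate 1 lay above control replicate 2. With somite stage in the model camera gave an adjusted p of 9.19e-07 (0.809 with an estimated correlation and 0.202 with fry), so a smaller share of surface ectoderm cells may contribute. With the mean marker level subtracted from each library, 0 of the 2 ridge genes still passed as lower in limma, 0 also at an unadjusted p under 0.05. This decides nothing, since the median SE of the 2 grew 4.15 times and Fgf8 went from -1.09 ± 0.14 to -0.64 ± 0.65. With the same subtraction and somite stage in the model, 2 of 2 stayed lower over the 11 ectodermal genes of the list. Fgf8 stood at -0.64 ± 0.06 and Sp6 at -0.95 ± 0.08 (limma, Benjamini-Hochberg adjusted p = 0.00137). En1 was also lower (0.00365), while 7 of the 11 lay above 0 and Dlx6 was higher at 0.70 ± 0.10 (0.00374). With stage in the model, the mean fall of the markers thus did not cover that of Fgf8 and Sp6. These 2 were picked because they had fallen, and the markers themselves ranged from -0.82 to -0.09. A smaller share of surface ectoderm cells as the whole cause is therefore not excluded. A smaller ridge within the ectoderm, or a lower output of each ridge cell after loss of Smarcc1 in the mesenchyme, stays open and was not tested.

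Lower Msx1, Msx2, Lhx2 and Lhx9 together with higher Pitx1 could come from the tissue that was dissected. Of 8 distal genes, 4 (Hoxa13, Hoxd13, Hoxd12 and Sall3) had 95% intervals wholly above the median of Msx1, Msx2, Lhx2 and Lhx9, -1.69. That median comes from genes picked because they had fallen, so it decides little by itself. The intervals of Hoxd13 (-0.62 to 0.24), Hoxd12 (-0.32 to 0.60) and Sall3 (-0.79 to 0.27) also lay above each of theirs, which reached up to -0.86 for Lhx9. The interval of Hoxa13 (-1.10 to -0.07) overlapped that of Lhx9. These intervals share that selection, and the comparison was chosen after the values were seen. They show unequal falls among the 8 distal genes, unlike an even loss of distal mesenchyme or its dilution by more proximal limb and body wall tissue. Neither is thereby excluded as the whole cause. The 8 proximal and flank genes tested, Meis1 and Meis2 among them, had a median of -0.0794, with 3 above 0 and 0 passing upward in limma (0 also at an unadjusted p under 0.05), but Osr2, of proximal mesenchyme, rose by 1.47 ± 0.17 (limma adjusted p of 0.0229, and 0.0781 and 0.0652 without control replicates 1 and 2), so some such tissue beside another cause stays open. For hindlimb tissue mixed into the samples, the other hindlimb genes gave a median of 0.57 over only 2 tested genes that went apart. These were Tbx4 at 1.55 ± 0.18 (limma adjusted p of 0.0229, with its call lost without control replicate 1) and Hoxc10 at -0.42 ± 0.22. Isl1 and Hoxc11 were too low to be tested. Isl1 stood at 1.09 and 0.800 TPM in the knockouts against 0.728 and 0.375 TPM in the controls. Hoxc11 stood at 0.858 and 0.577 against 1.27 and 0.909 TPM. Mixed-in hindlimb tissue thus cannot be told apart from a change in the cells. The genotype itself, with Pitx1 and Tbx4 rising in forelimb cells that lack Smarcc1, remains a hypothesis.

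With genotype in the model, 21 genes differed between the embryos with 40 and 39 somites, of which 4 are Y-linked and 13 are annotated pseudogenes. Rps2-ps10 stood at 2436 and 2394 TPM in the knockout and control with 40 somites and at 19.1 and 13.9 TPM with 39 somites, while its parent gene Rps2 went the other way, at 2811 and 2858 against 5236 and 5644 TPM. A candidate explanation is that reads were shared between pseudogenes and parent genes: over Rps2-ps10, Atp6v0c-ps2, Rps18-ps3 and Ptges3-ps, the parents lost 149.7% of the pseudogenes' gain in the knockouts and 152.4% in the controls, whereas the median ratio of 40 to 39 somites over 77 ribosomal protein genes with a mean above 50 TPM was 1.03 and 1.02. The loss above the gain was mainly that of Rps18, which was lower by more than Rps18-ps3 gained, and Gm10260, an unnamed gene model, was higher by 1323 and 1428 TPM. Stage, sex, a strain variant of the pseudogenes and any batch that follows them coincide in these embryos, were not tested and are balanced between genotypes.

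The 4 libraries can be split into 2 and 2 in only 3 ways, too few for a share under 0.05. The split by genotype gave 167 genes, the split by stage 13 and the remaining split 9, so that 1 of the 3 splits reached 167 and the highest other count was 13. At an unadjusted p under 0.05 in limma the counts were 1752, 1053 and 88. Genotype was not in the model of the other splits, so its differences add to their spread and lower their counts.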
